A study of Mus musculus with 11 samples.

How the data were processed

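Gene expression was measured in 11 samples of embryonic day 17 mouse kidney, each hybridised as biotin-labelled cRNA to 1 Affymetrix 3' expression array, per the labels' protocols. The source labels named 4 arrays wild-type and 7 arrays Robo2 homozygous. Of the 7 homozygous arrays, 3 carried titles with the letters NB, whose meaning is not given in the sources used here, and they were kept as a group of their own. The other 8 arrays belonged to the title series R2E17, with 1 wild-type and 1 homozygous array, or E17R2, with 3 and 3. Free-text labels on these samples also spoke of human brain tissue, which contradicts the organism and tissue labels. The organism, source and tissue labels were followed, and markers of brain and of other organs were measured on every array. Nothing in the labels says that the replicates came from separate animals. The p-values therefore measure only the spread between these samples, which may be technical.

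The authors deposited intensity values made with RMA, per the submitters' processing notes. The version of RMA and the handling of the scanner files are not given in the sources used here. All 45101 probe sets had values above 0 on a linear intensity scale, whereas the design had allowed for log2 values, so log2 of the deposited intensity was taken, with no pseudocount. The arrays fell into 2 sets with different distributions, which shows that they had been normalized apart. The first, called the set of 5 arrays, held the R2E17 arrays and the NB-titled arrays, with median intensities of 47.1 to 53.4 and 90th percentiles of 869 to 907. The second, called the set of 6 arrays, held the E17R2 arrays, with medians of 23.4 to 24.6 and 90th percentiles of 383 to 411. Spearman correlations over probe sets ran from 0.977 to 0.992 within the set of 5, from 0.982 to 0.993 within the set of 6, and from 0.954 to 0.973 between the sets. These are correlations across probe sets, which are not independent replicates. The number of arrays limits the precision.

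Probe sets were named from the platform annotation supplied for the array. After 64 control probe sets were set aside, 34958 probe sets had exactly 1 gene symbol, 932 had several and 9211 were not named here. Symbols were updated through the Entrez gene identifier with a RefSeq gene table of assembly GRCm38.p6, which held 34741 of the 34958. The table was used only for names and for gene order, and no coordinates are given. Each gene was represented by the probe set with the highest mean log2 intensity over the 11 arrays, which gave 18193 genes. For 1580 of them that probe set had a suffix that marks possible cross-hybridisation with related transcripts. No filter on dim genes was applied in the main analysis.

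Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend or robust settings, 2-sided) with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The linear model covered all 11 arrays, with a coefficient per group and a term for the title series. This term separates the normalized sets from the genotype, because each title series held as many wild-type as homozygous arrays. The first comparison was Robo2 homozygous minus wild-type over the E17R2 and R2E17 arrays (4 against 4). The second was NB-titled minus the other Robo2 homozygous arrays (3 against 4), with the 2 title series weighted by their arrays. In the second comparison 3 of the 4 reference arrays lay in the other normalized set, so the comparison carries the difference between the sets. Its values are given relative to the median shift of all genes. A contrast called within the set of 5 here was added after the data had been seen. It set the NB-titled arrays against the value that the model fitted for the 1 homozygous array normalized with them. That fitted value also draws on the R2E17 wild-type array and on the genotype difference fitted over both title series.

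Gene lists by cell type, pathway and neighbouring organ, 42 in number, were written before the data were examined, as were the tests, the groups and the rule for naming genes. The 41 lists with 3 or more measured genes were tested with camera in limma at a preset inter-gene correlation of 0.01, with the correlation estimated from the data, and with fry, each with Benjamini-Hochberg adjustment over the lists. The rule named Robo2, the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold, or the 5 with the smallest p per direction where fewer than 5 passed. From each list it allowed the members past the threshold, and otherwise up to 4 with the smallest p. From lists of other tissues, sex-linked, injury and early-response genes it also allowed the 3 with the highest mean. Genes outside the rule are said to be so where they appear. RNA quality was measured as the 3' minus 5' log2 value of the Gapdh and Actb control probe sets and compared with a 2-sided exact permutation test.

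The gene and list tests were tested on simulated data with the real residual spread, in which 200 of the 18193 genes were changed. In the genotype design, 89% of 100 genes changed by 1 on the log2 scale and 97% of 100 genes changed by 2 were recovered, with 9 false calls. In the contrast within the set of 5 the recovered shares were 65% and 95%, with 8 false calls. With no planted change 0 of 41 lists were called by camera, and a fall of 0.3 on the log2 scale planted in the proximal tubule list (-0.3) was recovered at an adjusted p of 6.53e-06 with 0 other lists called. The simulated genes were independent of each other, so this check says nothing about genes that vary together.

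Alternatives comprised a filter at the 40th percentile of mean intensity, quantile normalization over all arrays, centring on array medians, all probe sets separately, the mean of a gene's probe sets, and trend and robust eBayes. Further ones were array weights, covariates for the Y-linked mean and for the Gapdh ratio, other groupings and sets of arrays, the title series as a random effect (statmod 1.5.0), other thresholds, and leaving out each array in turn. Level-matched random lists, 10000 in number, and regroupings of the arrays were drawn with seed 1.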

Results

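Transcript levels were measured in embryonic day 17 mouse kidneys with and without a homozygous change of Robo2, which encodes a receptor for the guidance ligand Slit. In the developing kidney, Slit2 and Robo2 restrict where the ureteric bud grows out of the nephric duct. The arrays comprised 4 wild-type, 4 Robo2 homozygous and 3 Robo2 homozygous samples with a different title, called NB-titled here. Values are log2 of RMA intensities that had been normalized in a set of 5 arrays (wild-type replicate 1, homozygous replicate 1 and the NB-titled arrays) and a set of 6 arrays (replicates 2 to 4 of both genotypes). The median gene was 1.01 higher on the log2 scale in the R2E17 arrays of the set of 5 than in the set of 6. The genotype difference was therefore tested with this shift fitted. The planned NB-titled comparison crosses the sets and carries a shift of all genes, so a contrast within the set of 5 stands beside it. Log2 intensities of single arrays set side by side across the sets include the shift.

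Robo2 itself, read by 1 probe set, had the lower signal in the homozygous arrays of both title series. In the set of 6 its log2 intensity was 3.32 ± 0.31 (SD, n = 3) in wild-type and 2.24 ± 0.19 (SD, n = 3) in homozygous kidneys. The single R2E17 arrays had 3.96 in wild-type and 3.37 in homozygous. The fitted log2 difference was -0.96 ± 0.19 (SE), with an unadjusted p of 5.613e-04 and a Benjamini-Hochberg adjusted p of 0.879 in limma, so it did not pass over all genes. Adjusted over the list alone, Robo2 passed among 20 Slit-Robo signalling genes. The signal was dim: in the set of 6 Robo2 ranked at percentiles 26.1 to 38.1 of its array in wild-type and 3.37 to 9.54 in homozygous samples. In the set of 5 the NB-titled arrays read 3.28, 3.86 and 3.99, and the last 2 values lay nearer to the wild-type array (3.96) than to the homozygous one (3.37). Which part of the gene the probe set reads relative to the altered part is not given in the sources used here, so Robo2 does not check the labels of the NB-titled arrays.

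The first comparison asked which transcripts differed between Robo2 homozygous and wild-type kidneys. No single gene passed the test. Lists of maturing nephron segments, podocytes and endothelium were lower in camera, where 18 of 41 lists passed, but 0 lists passed with an estimated correlation (smallest adjusted p = 0.372) and 0 in fry (smallest adjusted p = 0.313). Umod, which encodes the urinary protein uromodulin of the thick ascending limb, had a log2 intensity of 8.29 ± 0.24 in wild-type and 7.41 ± 0.64 in homozygous kidneys (SD, n = 3 each, set of 6) and was 1.01 lower in the R2E17 pair (-1.01). Syt13, a synaptotagmin, stood out in the other direction, with 5.08 ± 0.17 in wild-type and 5.95 ± 0.15 in homozygous kidneys (SD, n = 3 each, set of 6) and a difference of 0.82 in the R2E17 pair.

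Of 18193 genes, 0 passed an adjusted p of 0.05 in limma with Benjamini-Hochberg adjustment, and 875 had an unadjusted p under 0.05, against 910 by chance. Syt13 had the smallest adjusted p (0.0651), with a log2 difference of 0.86 ± 0.09 (SE). The model's spread also drew on the NB-titled arrays, which lie outside this comparison and read 6.28, 6.27 and 6.28 for Syt13. Pairs of arrays shared 4633 to 6876 identical values in the set of 5 and 112 to 236 in the set of 6. Whether such ties lowered the spread was not tested. The smallest limma adjusted p of any gene was 0.7065 with only the 8 arrays of the comparison and 0.8397 with only the E17R2 arrays. A second, dimmer Syt13 probe set gave 0.06. The next genes with higher values were Ly6h (0.83 ± 0.14, SE), Spdye4a (0.49 ± 0.08), Eml6 (0.37 ± 0.07) and the zinc finger gene Zfp853 (0.36 ± 0.06), at limma adjusted p values of 0.807 to 0.879. The other 2 Eml6 probe sets gave -0.08 and 0.05. On the lower side the smallest p values after Robo2 belonged to the epidermal growth factor receptor ligand Tgfa (-0.32 ± 0.06), the organic anion transporter Slco1a4 (-0.51 ± 0.11), Tnfaip2 (-0.52 ± 0.12) and Zfp612 (-0.29 ± 0.07), at limma adjusted p values of 0.879 to 0.943. Their dimmer probe sets gave -0.08 and 0.06 for Tgfa, -0.39 and 0.06 for Tnfaip2 and 0.15 for Zfp612. These 9 genes had the same sign in the R2E17 pair as in the set of 6.

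**Figure D1:**
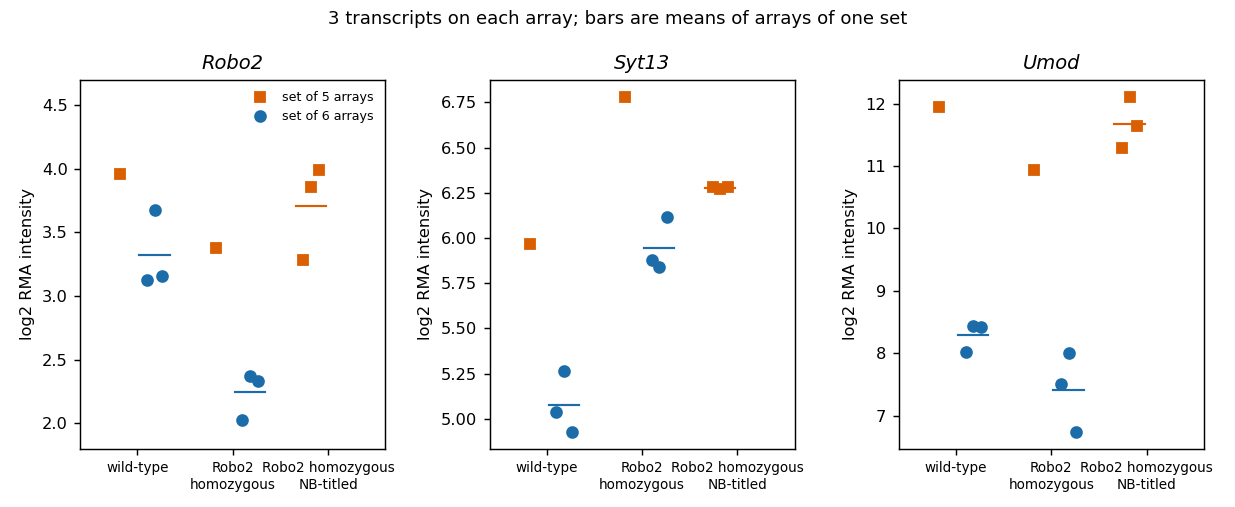
Log2 RMA intensity (vertical axis) of Robo2, Syt13 and Umod on each array, by group; orange squares are the set of 5, blue circles the set of 6, and bars are means of arrays of one set. In the set of 6 the wild-type and homozygous arrays had means of 3.32 and 2.24 for Robo2, 5.08 and 5.95 for Syt13, and 8.29 and 7.41 for Umod.

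Genes of most nephron segments were lower by small amounts, in camera with Benjamini-Hochberg adjustment. In the list of the renal vesicle to the S-shaped body, the first epithelial stages of the nephron, 21 of 22 genes lay below the median gene, with a list median of -0.23 on the log2 scale (camera adjusted p = 5.38e-10; adjusted p = 0.374 with an estimated correlation). Its members with the smallest p were the BMP-binding gene Bmper (-0.42 ± 0.11, SE), the cadherin Cdh6 (-0.44 ± 0.13) and the Iroquois factors Irx1 (-0.42 ± 0.15) and Irx2 (-0.34 ± 0.12). For podocytes, 25 of 30 genes were below, with a list median of -0.19 (camera adjusted p = 3.32e-08; adjusted p = 0.372 with an estimated correlation). Lmx1b, a transcription factor required in podocytes, differed by -0.54 ± 0.14 (SE) and Ptpro, a podocyte receptor phosphatase, by -0.57 ± 0.17, although both were slightly higher in the R2E17 pair (0.08 and 0.14). In the loop of Henle list, 15 of 16 genes lay below the median gene (median -0.27, camera adjusted p = 1.30e-07; adjusted p = 0.372 with an estimated correlation), among them Umod (-0.91 ± 0.26, SE) and the potassium channel gene Kcnj1 (-0.64 ± 0.21). The list median was -0.36 in the set of 6 and 0.0066 in the R2E17 pair. The distal convoluted and connecting tubule list had 13 of 14 genes below (median -0.33, camera adjusted p = 3.205e-08; adjusted p = 0.372 with an estimated correlation). It included Slc12a3, the thiazide-sensitive sodium chloride cotransporter (-0.85 ± 0.27, SE), and the calcium-binding protein gene S100g (-0.58 ± 0.21).

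In the proximal tubule list 33 of 37 genes lay below the median gene, with a median of -0.32 (camera adjusted p = 1.85e-06; adjusted p = 0.573 with an estimated correlation). The sodium phosphate cotransporter gene Slc34a1 (-0.54 ± 0.28, SE) and the fatty acid transporter gene Slc27a2 (-0.50 ± 0.22) were among its members. In homozygous replicate 4 their log2 intensities were 6.94 and 7.56, below homozygous replicates 2 and 3 (8.19 and 8.13 for Slc34a1, 8.47 in each for Slc27a2). Both genes were higher in the homozygous array of the R2E17 pair (10.82 against 10.69, and 11.67 against 11.51). The median of this list was -0.61 in the set of 6 and 0.55 in the R2E17 pair, so the 2 title series had opposite signs. The wild-type array of that pair stood apart in RNA quality. Endothelial genes were lower by about the same amount in both title series, with medians of -0.17 each, and 19 of 21 lay below the median gene (camera adjusted p = 3.205e-08; adjusted p = 0.374 with an estimated correlation). Examples were Plvap, which forms the diaphragms of fenestrated endothelium (-0.39 ± 0.11, SE), the tight junction gene Cldn5 (-0.49 ± 0.16) and the angiopoietin receptor gene Tek (-0.31 ± 0.12). Homozygous replicate 4 carried smooth muscle transcripts. Without it the fitted median was -0.070 for proximal tubule genes (camera adjusted p = 0.0374), -0.16 for renal vesicle (8.23e-08), -0.12 for podocyte (6.94e-07), -0.20 for loop of Henle (6.37e-07) and -0.13 for endothelial genes (1.34e-06). In the set of 6 alone the proximal tubule median went from -0.61 to -0.35 without that array.

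Lists of the collecting system and of regulatory genes were lower in camera as well. Intercalated cell genes, such as the proton pump subunit Atp6v0d2 (-0.51 ± 0.15, SE) and the ammonia transporter Rhcg (-0.39 ± 0.16), had a median of -0.18 (camera adjusted p = 0.0013; adjusted p = 0.547 with an estimated correlation), with -0.37 in the set of 6 and 0.020 in the R2E17 pair. Principal cell genes of the collecting duct had a median of -0.16, with 18 of 23 below the median gene (camera adjusted p = 0.0016; adjusted p = 0.563 with an estimated correlation). Without homozygous replicate 4 the fitted median was -0.096 for intercalated (camera adjusted p = 0.0642), -0.048 for principal cells (0.0957) and -0.091 for GDNF-RET genes (0.0048). In the list of GDNF-RET signalling and ureteric bud induction, the pathway that Robo2 limits in space, 17 of 21 genes lay below, with a median of -0.17 (camera adjusted p = 6.34e-05; adjusted p = 0.419 with an estimated correlation). Lhx1 differed by -0.46 ± 0.18 (SE) and Gfra1, the GDNF co-receptor, by -0.22 ± 0.10. Homozygous replicate 4 carried part of this, with log2 intensities of 7.87 for Lhx1 and 8.31 for Gfra1. Homozygous replicates 2 and 3 had 8.76 and 8.72 for Lhx1 and 8.63 and 8.56 for Gfra1. Genes of congenital kidney anomalies had a median of -0.15 (25 of 30 below, camera adjusted p = 3.32e-04; adjusted p = 0.372 with an estimated correlation), and without either R2E17 array their camera adjusted p was 0.0656. The glomerular basement membrane and laminin list, with Lama5 at -0.21 and Col4a6 at 0.35, had a median of -0.10 (camera adjusted p = 0.0029; adjusted p = 0.419 with an estimated correlation), and a camera adjusted p of 0.349 without either R2E17 array.

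Nephron progenitor genes (median -0.15), fibroblast growth factor signalling (-0.09), the renin-angiotensin system (-0.18) and erythroid genes (-0.22) were also lower, at camera adjusted p values of 0.0242, 0.0186, 0.0088 and 0.035. Their adjusted p values with an estimated correlation were 0.547, 0.419, 0.464 and 0.706. Each of these 4 lists lost its call when 1 array was left out. Over such fits the medians ran from -0.22 to -0.037 for progenitors and from -0.13 to -0.038 for fibroblast growth factor signalling. They ran from -0.24 to -0.11 for the renin-angiotensin system and from -0.33 to -0.11 for erythroid genes. As camera adjusted p, progenitors were at 0.0506, 0.0772 and 0.345 without wild-type replicate 3, homozygous replicate 3 or homozygous replicate 4. Fibroblast growth factor signalling was at 0.0849 and 0.0905 without wild-type replicate 3 or homozygous replicate 4, erythroid genes at 0.677 and 0.802 without wild-type replicate 4 or homozygous replicate 3, and the renin-angiotensin system at 0.0656 without either R2E17 array. Interferon response genes were higher, with a median of 0.27 and 12 of 15 above the median gene (camera adjusted p = 0.0047; adjusted p = 0.547 with an estimated correlation). That shift came from the R2E17 pair, with a list median of 0.74 against 0.03 in the set of 6, where the camera adjusted p was 0.54, and the pair's wild-type array stood apart in RNA quality. Ifi27, an interferon-induced gene, differed by 0.47 ± 0.14 (SE).

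Markers of neighbouring tissue also passed camera in this comparison, with values that a few arrays carried. Smooth muscle genes were higher, with a median of 0.50 and 14 of 15 above the median gene (camera adjusted p = 0.0242; adjusted p = 0.819 with an estimated correlation). Without homozygous replicate 4 the median turned to -0.20 (camera adjusted p = 9.36e-06), and without wild-type replicate 3 or 4 the camera adjusted p was 0.0603 or 0.236. That array had a log2 intensity of 12.8 for the smooth muscle actin gene Actg2, against 6.65 ± 0.75 (SD, n = 5) in the rest of the set of 6, and its proximal tubule list was the lowest of that set, 0.92 below the set's mean (-0.92). Adrenal genes were lower in homozygous arrays, with a median of -0.88 and 15 of 15 genes below the median gene (camera adjusted p = 3.58e-05; adjusted p = 0.547 with an estimated correlation). Their median ran from -1.76 to -0.57 with 1 array left out, and was -1.18 in the set of 6 and -0.026 in the R2E17 pair. Hsd3b1, a steroid-producing enzyme of the adrenal gland, read 10.6 and 10.4 in wild-type replicates 2 and 3, 8.90 in homozygous replicate 2, and at most 5.44 in the other arrays of those groups. Relative to the mean of its set, homozygous replicate 2 had the adrenal list at -0.13 and the gonad list at 1.51, so the organ behind its Hsd3b1 signal was not determined. Liver genes (median -0.49, camera adjusted p = 0.188), skeletal muscle (0.81, 0.139) and gonad genes (0.32, 0.0803) did not pass.

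Slit-Robo signalling genes did not pass as a group: 10 of 20 lay below the median gene (camera adjusted p = 0.245). Adjusted over the list alone, 2 of its genes passed, Robo2 and the Slit-Robo GTPase-activating gene Srgap1 (-0.28 ± 0.07, SE), and 0 passed over all genes in limma. The same count adjusted over the list alone was 1 for congenital anomaly genes and 1 for podocyte genes, in both cases Robo2. It was 1 for hypoxia genes, the hypoxia-induced gene Ndrg1 (-0.42 ± 0.10, SE), 1 for TGF beta and BMP signalling, the activin subunit gene Inhba (0.93 ± 0.21), and 0 for every other list. Inhba differed in the set of 6 (5.11 ± 0.26 against 6.35 ± 0.22, SD, n = 3 each) and by 0.00 in the R2E17 pair. Stromal genes had a median of 0.07 (camera adjusted p = 0.168) and macrophage genes one of 0.08 (0.0948). Cell cycle genes (0.02, camera adjusted p = 0.873), fetal genes (-0.01, 0.981), Wnt signalling (0.00, 0.783), ureteric bud tip genes (-0.09, 0.745) and urothelial genes (-0.02, 0.597) did not pass either.

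**Figure D2:**
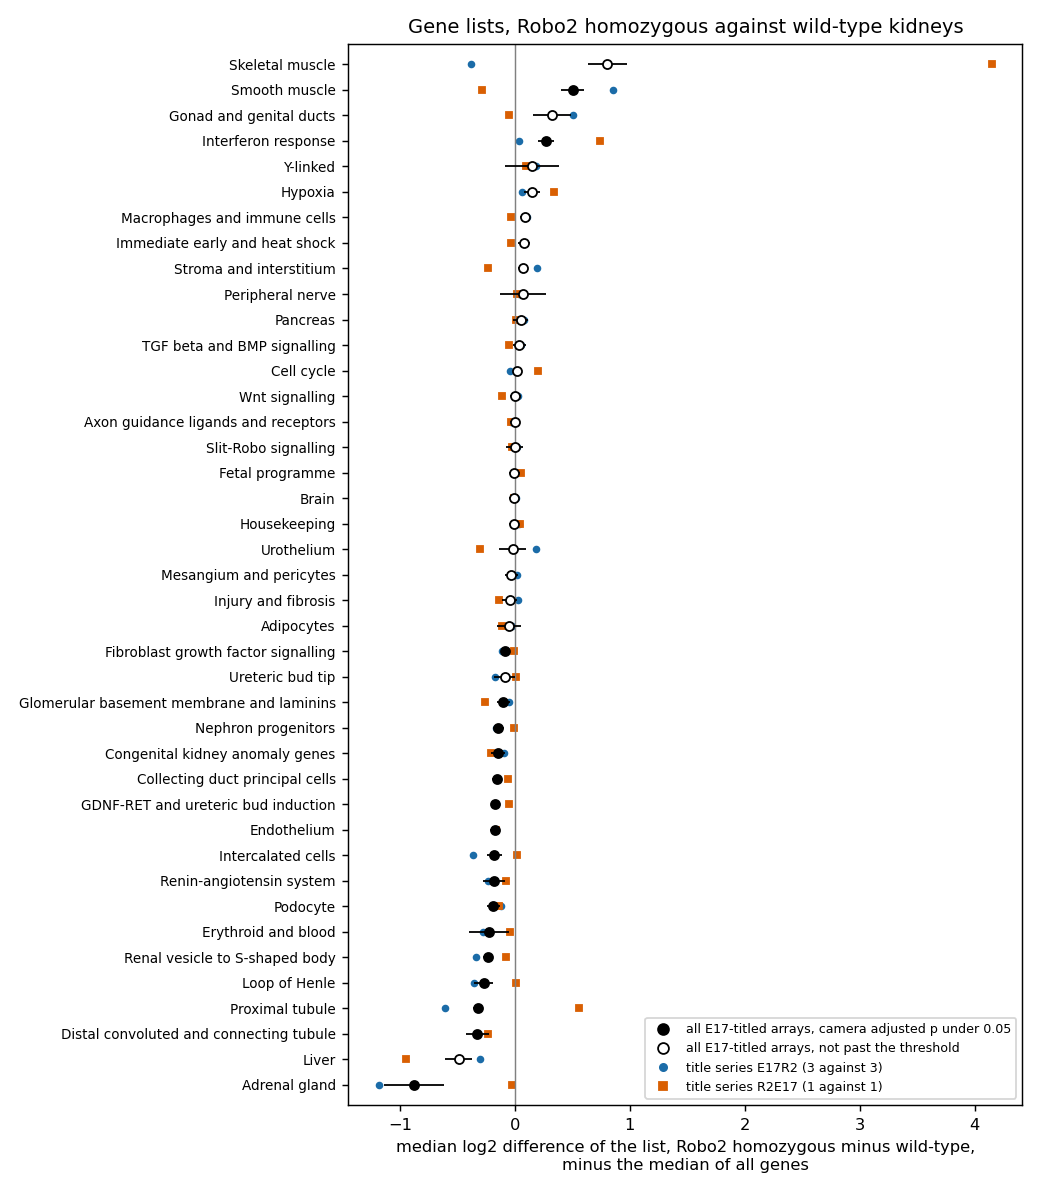
Median log2 difference of each of the 41 gene lists, Robo2 homozygous minus wild-type, minus the median of all genes (horizontal axis), with the standard error of the median over genes; filled circles passed camera, blue and orange marks are the set of 6 alone and the single R2E17 pair. Of the 18 filled lists 16 lie below 0, from -0.09 to -0.88, and 4 of the 18 have the opposite sign in the R2E17 pair.

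Of the 41 lists, 18 passed camera, 16 lower and 2 higher. With an estimated correlation 0 passed (smallest adjusted p = 0.372), and fry called 0 (smallest adjusted p = 0.313). The 8 lists that passed in every fit with 1 array left out were GDNF-RET signalling, renal vesicle, podocyte, proximal tubule, loop of Henle, distal tubule, endothelium and adrenal gland. Of the 18 lists, proximal tubule, loop of Henle, intercalated cells and smooth muscle had a median of the opposite sign in the R2E17 pair.

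RNA quality and sex-linked transcripts were measured as checks on the groups. The 3' minus 5' log2 value of Gapdh was 0.0661 ± 0.0234 in homozygous and 0.229 ± 0.322 in wild-type arrays (SD, n = 4 each, 2-sided exact permutation p = 0.457, Benjamini-Hochberg adjusted over 4 such tests 0.6). For Actb the difference was -0.14 (exact permutation p = 0.6, adjusted 0.6). Wild-type replicate 1, the only wild-type array of the R2E17 pair, had 0.70 for Gapdh and 1.12 for Actb, against at most 0.22 and 0.75 on the other 10 arrays. The Y-linked genes Kdm5d, Eif2s3y and Uty gave signal in 1 of 4 wild-type, 1 of 4 homozygous and 3 of 3 NB-titled arrays, and Xist, the transcript that silences an X chromosome in female cells, was at 4.57 to 4.89 there against 10.8 to 12.5 in the other 6 arrays.

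The second comparison set the NB-titled homozygous kidneys against the other homozygous kidneys, of the same genotype and tissue label. Within the set of 5, where values share one normalization, the only other homozygous array was replicate 1, assumed to vary like the other groups. The contrast used the value fitted for this lone array. That fitted value also draws on wild-type replicate 1 and on the genotype difference fitted over both title series. Values of the contrast are therefore not the NB-titled mean minus homozygous replicate 1 itself. Homozygous replicate 1 carried skeletal muscle transcripts (list score 2.65 above the mean of its set). The Y-linked mean was 6.79, 7.02 and 6.94 in NB-titled replicates 1 to 3. It was 3.16 in homozygous replicate 1 and 3.01 in wild-type replicate 1, which lacked Y-linked signal. Sex of the animals and NB title therefore cannot be told apart within the set of 5. Values and p-values of this contrast hold against the fitted reference and not for homozygous kidneys as a group. Against the fitted reference, proximal tubule genes lay higher by a median of 0.28, with 31 of 37 above the median gene. The camera adjusted p was 1.09e-04, and 0.62 with an estimated correlation. Relative to the mean of the set, this list stood at 0.23 in homozygous replicate 1 and -0.34 in wild-type replicate 1. In the NB-titled arrays it stood at 0.04, 0.24 and -0.12, so the rise did not hold against homozygous replicate 1 itself. Umod was 0.69 ± 0.36 higher (SE) and Slc12a3 0.60 ± 0.37. No single gene passed.

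In that contrast 0 of 18193 genes passed in limma with Benjamini-Hochberg adjustment (smallest adjusted p = 0.9999), and 306 had an unadjusted p under 0.05. The smallest p values belonged to the flavoprotein gene Rnls (0.69 ± 0.15, SE), the glucuronosyltransferase-family gene Ugt3a2 (1.248 ± 0.27), Ocel1 (0.82 ± 0.18), the Y-linked gene Uty (2.85 ± 0.65) and the alkaline phosphatase gene Alpl (0.55 ± 0.13). On the lower side they were Uxs1 (-0.79 ± 0.18), Syt13 (-0.52 ± 0.13), Copg2 (-0.47 ± 0.11), the muscle ubiquitin ligase gene Trim63 (-0.55 ± 0.14) and Ccdc71 (-0.48 ± 0.12). Robo2 was 0.52 ± 0.26 higher (SE, limma adjusted p = 0.9999).

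Among the lists, and against that fitted reference alone, hypoxia genes were lower by a median of -0.29 (camera adjusted p = 5.36e-07). Cell cycle genes were lower by -0.13, with 29 of 31 below the median gene (camera adjusted p = 4.23e-05). The glucose transporter gene Slc2a1 differed by -0.66 ± 0.32 (SE) and the kinase gene Pdk1 by -0.49 ± 0.22. Macrophage genes were higher by a median of 0.30 (camera adjusted p = 5.90e-07), with the lysozyme gene Lyz2 at 0.74 ± 0.23 (SE), and injury genes by 0.10 (3.04e-04), with Lcn2 at 1.06 ± 0.42. Endothelial genes were higher by 0.15 (6.81e-04), distal tubule genes by 0.16 (0.0054), loop of Henle genes by 0.15 (0.0074) and principal cell genes by 0.13 (0.0074), each in camera. With an estimated correlation the adjusted p was 0.387 for injury genes and 0.62 for each of the other 7 of these lists. Other tissues moved in the same contrast: liver genes by 2.05 (camera adjusted p = 6.53e-05), adrenal genes by 1.47 (1.63e-08), peripheral nerve by 1.36 (0.0047), urothelium by 0.30 (0.0028), erythroid genes by 0.38 (0.0397) and skeletal muscle by -1.40 (0.0039), each with an adjusted p of 0.62 with an estimated correlation. Single arrays carried the nerve, liver and adrenal values: relative to the mean of the set, the nerve list stood at 2.96 in NB-titled replicate 3 against -0.78 and -0.46 in the other NB-titled arrays and -0.78 in homozygous replicate 1. In NB-titled replicate 2 the liver list stood at 3.99 and the adrenal list at 2.27, against at most -0.34 and -0.28 in NB-titled replicates 1 and 3 and homozygous replicate 1. On this scale cell cycle genes stood at 0.26, -0.26 and -0.11 in NB-titled replicates 1 to 3, against 0.19 in homozygous replicate 1. Principal cell genes stood at 0.26, -0.13 and -0.068 against -0.055, and distal tubule genes at -0.259, 0.155 and 0.096 against -0.117. Loop of Henle genes stood at -0.14, 0.14 and 0.015 against -0.033. For hypoxia, macrophage, injury and endothelial genes each NB-titled array lay on the same side of homozygous replicate 1. Y-linked genes moved by 4.17 (camera adjusted p = 1.51e-07; adjusted p = 0.387 with an estimated correlation). Adjusted over the list alone, 3 of 3 Y-linked genes and 1 of 23 principal cell genes passed, and 0 in any other list. Alb, the plasma albumin made by liver, read 13.8 in NB-titled replicate 2 and 5.62 in homozygous replicate 1. The muscle actin gene Acta1 read 11.9 in NB-titled replicate 3 and 11.6 in homozygous replicate 1, against 5.54 and 5.62 in NB-titled replicates 1 and 2. In this contrast 16 lists passed camera, 0 passed with an estimated correlation and 0 passed in fry.

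**Figure D3:**
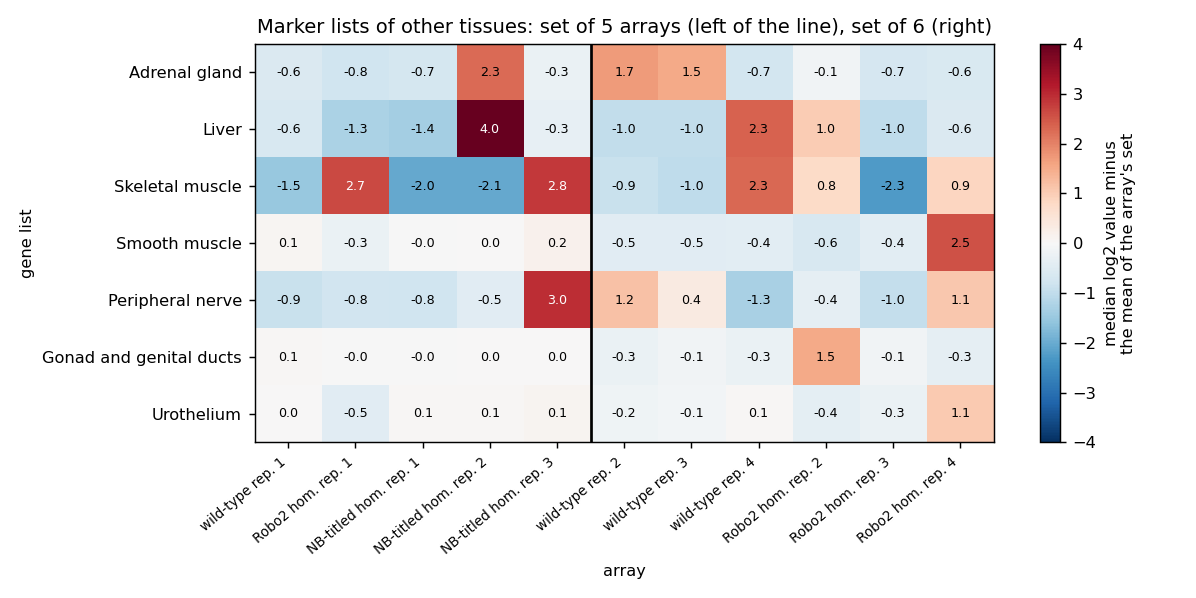
Median log2 intensity of 7 marker lists of other tissues (vertical) on each array (horizontal), minus the mean of the array's set, by colour and printed value; the line parts the set of 5 from the set of 6. NB-titled replicate 2 stands at 3.99 for liver and 2.27 for adrenal gland, and homozygous replicate 4 at 2.53 for smooth muscle.

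The comparison as planned, against all 4 other homozygous arrays, gave 15566 of 18193 genes past the threshold in limma with Benjamini-Hochberg adjustment, 15509 higher and 57 lower, because the median gene was shifted by 0.77. With each array centred on its median the count was 7151, with 1928 higher and 5223 lower, and with quantile normalization over all arrays it was 4773, with 2353 higher and 2420 lower. Relative to the shift, the largest rises included Cyp27b1, which activates vitamin D (4.52), and Kap, the kidney androgen-regulated protein of the proximal tubule (3.63). The gluconeogenic genes G6pc (3.45) and Pck1 (2.78), Cyp24a1 (2.90) and Cyp2e1 (2.72) were also among them. Serpina6 (3.73), Ranbp3l (3.04) and the Y-linked genes Eif2s3y (3.43) and Kdm5d (3.02) completed the 10. Among the largest falls were Xist (-5.85), the embryonic globin gene Hbb-y (-4.54), the germ cell gene Dazl (-2.36) and Bmp5 (-2.20). The glycogen-targeting subunits Ppp1r3b (-1.64) and Ppp1r3c (-1.64), 2310034C09Rik (-2.13), Lrfn5 (-1.80), Krtap13 (-1.65) and Slitrk4 (-1.65) made up the rest. Some of these were dim: in the set of 5 Krtap13 had a log2 intensity of 2.75 on every array, 2310034C09Rik 2.67 to 2.75 and Dazl 2.58 to 2.93. Such genes may not follow the shift taken off. Before it their differences were -0.88, -1.36 and -1.59. In the contrast within the set of 5, against its fitted reference, the differences were 1.14 ± 0.83 for Cyp27b1, 0.53 ± 0.38 for Kap, 0.54 ± 0.33 for G6pc, -0.07 ± 0.38 for Pck1 and -1.26 ± 0.37 for Hbb-y (SE), all with a limma adjusted p of 0.9999. The NB-titled mean and homozygous replicate 1 itself had log2 intensities of 10.22 and 9.98 for Cyp27b1, 12.23 and 11.83 for Kap, and 9.78 and 9.41 for G6pc. For Pck1 they were 9.91 and 10.41, and for Hbb-y 3.38 and 5.18. In the planned comparison Robo2 was 0.42 higher beyond the shift.

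Of the lists in the planned comparison, 14 passed camera, 3 higher and 11 lower, relative to all genes. With an estimated correlation 0 passed (smallest adjusted p = 0.0785). Camera compared t values that still held the shift of all genes. Genes that vary widely between arrays have small t values there, so their lists can be called lower whatever their level. The lower calls of this comparison therefore do not by themselves show lower levels. Of 13 skeletal muscle genes 0 passed in limma. Adjusted over the list alone, 37 of 37 proximal tubule and 20 of 20 Slit-Robo genes passed, as they did over all genes, before the shift is taken off. The higher ones were proximal tubule (median 1.57, camera adjusted p = 0.0127, and 0.0941 without dim genes), endothelium (0.46, 0.0095) and glomerular basement membrane (0.45, 0.0095). The lower ones included skeletal muscle (-1.75, camera adjusted p = 6.62e-20), gonad (-0.78, 1.44e-12), smooth muscle (-0.14, 4.39e-09), peripheral nerve (-0.32, 3.405e-08), fetal genes (-0.39, 1.88e-05), hypoxia (-0.23, 1.57e-04), erythroid genes (-0.17, 2.96e-04) and cell cycle (-0.27, 0.036). Without homozygous replicate 4 smooth muscle lost its call and turned to 0.35 (camera adjusted p = 0.456), and over the fits with 1 array left out the medians ran from -1.30 to 0.06 for nerve, -3.23 to -0.87 for skeletal muscle, -1.09 to -0.45 for gonad and -0.34 to -0.027 for erythroid genes. Cell cycle lost its call in 3 of 11 such fits (highest camera adjusted p = 0.553). With an estimated correlation the adjusted p was 0.747 for proximal tubule and cell cycle, 0.722 for endothelium, 0.584 for basement membrane, smooth muscle and nerve, 0.224 for skeletal muscle and gonad, 0.0785 for fetal genes, 0.674 for hypoxia and 0.627 for erythroid genes. Camera gave a lower direction for urothelium, adrenal gland and liver at adjusted p values of 0.0047, 9.68e-05 and 1.44e-06, while their medians were 0.20, 0.62 and 0.83, so median and test differed in sign, and urothelium lost its call without homozygous replicate 4 (camera adjusted p = 0.658). With 1 array left out the medians ran from 0.048 to 1.39 for adrenal gland and from -0.66 to 2.07 for liver, with both lowest values without NB-titled replicate 2. Their adjusted p values with an estimated correlation were 0.722, 0.674 and 0.627. NB-titled kidneys and the normalized set cannot be told apart in this comparison except for the 1 reference array within the set of 5. The Gapdh 3' minus 5' value was 0.142 ± 0.0969 (SD, n = 3) in NB-titled and 0.0661 ± 0.0234 (SD, n = 4) in the other homozygous arrays (exact permutation p = 0.229, adjusted 0.457), and for Actb the difference was 0.19 (exact permutation p = 0.0857, adjusted 0.343). The smallest p such a test allows with 3 against 4 arrays was 0.0286.

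**Figure D4:**
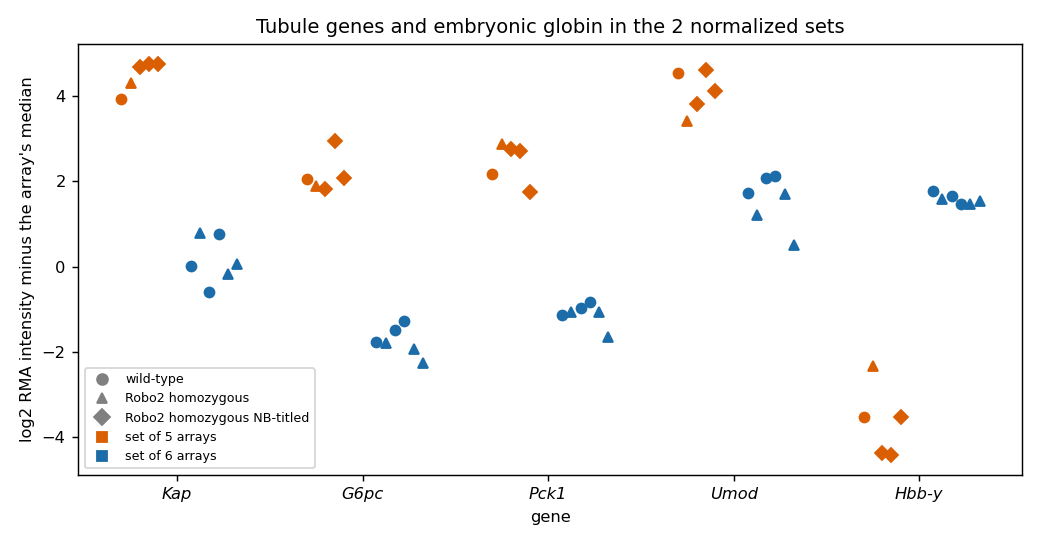
Log2 RMA intensity minus the array's median (vertical axis) of 5 genes (horizontal axis) on each array; colour gives the normalized set and shape the group. Each of Kap, G6pc, Pck1 and Umod lies higher on every array of the set of 5 than on any of the set of 6, with means of 4.49 and 0.14 for Kap, and Hbb-y lies lower, at -3.64 and 1.59.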

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

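The tests of adrenal tissue, sex, normalization, other-organ tissue and stage for the normalized sets and the test on endothelial and stromal genes were chosen only after the result was seen.

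Values in this part are log2 intensities minus the median of the array unless said otherwise. Of 106 combinations of a group of 4 arrays with a gene or list, 16 had 1 array far from the other 3. Chance gives about 1 in 20, or 5.3, and 10 of the 16 lay in wild-type or homozygous replicate 1, the only arrays of their groups from the other normalized set.

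In homozygous replicate 4, smooth muscle genes had a median of 4.42 against 0.63 to 0.97 in the other homozygous arrays. The same array had the lowest value for renal vesicle genes, 1.40 against 2.01 to 2.05, and the highest for immediate early genes, 1.19 against 0.73 to 0.80. Besides Actg2, the genes that stood furthest above the other 5 arrays of the set, chosen after their values were seen, included the smooth muscle genes Cnn1 (5.78 higher) and Myh11 (4.80) and the basal keratin gene Krt15 (4.59).

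In wild-type replicate 1, endothelial genes had a median of 2.25 against 1.61 to 1.70 in the other wild-type arrays, axon guidance genes 1.48 against 1.17 to 1.21, and fetal genes 2.20 against 2.76 to 2.83. In homozygous replicate 1, distal tubule genes had a median of 1.49 against 0.56 to 0.57, and interferon response genes had -0.27 against -1.05 to -0.99. Single genes that stood apart were Zfp853, at -2.51 in wild-type replicate 1 against -2.01 to -1.93 and at -2.31 in homozygous replicate 1 against -1.61 to -1.54. In the same homozygous array Spdye4a was at -4.10 against -2.63 to -2.54, Eml6 at -3.07 against -2.03 to -1.96, and Zfp612 at -0.21 against -0.63 to -0.62.

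Liver genes had a median of 2.79 in wild-type replicate 4 against -1.07 to -0.47 in the other wild-type arrays. Y-linked genes had a median of -1.30 in wild-type replicate 4 against -4.30 to -3.90, and of -0.73 in homozygous replicate 2 against -4.38 to -4.01.

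Each arm of the R2E17 genotype difference was 1 array, without a replicate and assumed to vary like the other groups. Set against the difference in the set of 6, it gave 3 of 18193 genes in limma with Benjamini-Hochberg adjustment, each resting on homozygous replicate 1, and 2015 with an unadjusted p under 0.05. For Ang, which encodes angiogenin, the genotype difference of the R2E17 pair minus that of the set of 6 was -3.32 (limma adjusted p = 0.0015): homozygous replicate 1 had a log2 intensity of 4.66 and every other array one between 7.84 and 8.19. Rpgrip1 differed by -2.33 (limma adjusted p = 0.0021), with 6.40 in homozygous replicate 1 and 8.71 to 8.997 elsewhere, and 14 measured genes lie between it and Ang on their chromosome. For Nat8f2 the difference was 1.90 (limma adjusted p = 0.0208), with 5.90 in homozygous replicate 1, 3.999 in wild-type replicate 1 and 3.23 to 3.27 in the set of 6. These 3 genes were chosen after their values were seen.

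Kidney cell lists that were lower in Robo2 homozygous kidneys, 10 in number, are the first pattern weighed. In the same direction, 7 of the 10 still passed camera without homozygous replicate 4, so these 7 calls did not need that array. With the Gapdh value as a covariate 9 of 10 still passed, and 10 of 10 with the adrenal list level of each array. Another split of the 8 arrays moved 9 kidney lists past camera in one direction. Passing camera therefore cannot decide on muscle-rich material, RNA quality or adrenal tissue. The Gapdh value stood apart only on wild-type replicate 1 (0.70, against at most 0.22 elsewhere). Its covariate says little about RNA quality in the set of 6. Homozygous replicate 4 carried part of the size, since without it the medians in the set of 6 went from -0.34 to -0.18 for renal vesicle, from -0.37 to -0.15 for intercalated and from -0.16 to -0.022 for principal cells, and the fitted proximal tubule median from -0.32 to -0.070. A lower share of nephron cells was predicted to raise stroma, endothelium and macrophages alike. In the fit endothelial genes were at -0.17 while stromal genes were at 0.07 and macrophage genes at 0.08. The gap of 0.256 exceeded a spread (2 summed standard errors over genes) of 0.166. These genes vary together, and the spread between arrays was not used. In the R2E17 pair stromal genes (-0.23) lay below endothelial genes (-0.17), with macrophage genes at -0.03. A lower share of nephron cells therefore stays open. Chance could not be excluded for the number of lists: 6 of the 35 splits of the 8 arrays gave 18 or more lists, and the highest of the other splits gave 22. That split put both R2E17 arrays on one side, unlike the real split. Among the splits that parted the R2E17 pair the highest gave 20 lists. An effect of the Robo2 genotype on nephron maturation may therefore remain only as one open explanation beside chance and the causes named above.

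The second pattern was tubule genes in the set of 5 above those in the set of 6, for which no biological group in the labels offered a test. Separate normalization as the whole cause was argued against by the proximal tubule list, 1.68 above all genes on the log2 scale, since 10000 random lists matched on level reached at most 0.38. The 1.68 was itself measured in the 2 R2E17 arrays, both without Y-linked signal; against only the 4 arrays of the set of 6 without it the excess was 1.86 (1.54 and 2.14 for the 2 arrays), which argues against the sex of the animals, and nephron progenitor genes at 0.012 argue against a general dilution by other organs in the set of 6. A later developmental stage in the set of 5, although all labels say embryonic day 17, predicted 6 list directions. In the R2E17 arrays 5 were seen, with progenitors at 0.012 (SE over genes 0.11) as the exception. In the NB-titled arrays, left out of this count, progenitors were at -0.12. Proximal tubule genes were at 1.82, loop of Henle at 0.89, distal tubule at 0.90, cell cycle at -0.30 and fetal genes at -0.53 there. These are the 6 predicted directions. Stage and set cannot be told apart. Batch-dependent probe response that differs between transcripts was not tested and stays open.

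The third pattern concerned genes near Robo2, since alleles linked to the altered locus could differ between the genotypes. Among the 100 measured genes closest to Robo2 in gene order, 8 had an unadjusted p under 0.05 in the genotype comparison, against 866 of 18092 other genes (4.79%; 1-sided Fisher's exact p = 0.108), so linked alleles could be neither shown nor excluded. The neighbour with the smallest p was Senp7, 36 measured genes away, at 0.74 ± 0.15 (SE, limma adjusted p = 0.879), while its 2 other probe sets gave 0.02 and -0.03.

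For the genotype gene count of 0 in limma, the count over splits tests nothing, since each of the 35 splits gives at least 0; the highest of the other splits gave 4 genes. Of those 35 splits, 17 gave at least the real 875 genes with an unadjusted p under 0.05, and the highest of the others gave 2191. The splits with 4 and 2191 put both R2E17 arrays on one side. Among the splits that parted the R2E17 pair the highest counts were 0 and 1528. For the NB-titled comparison 2 of the 35 splits gave at least the real 15566 genes, and the highest other split gave 15666. That split set 3 arrays of the set of 6 apart from the rest, so it followed the normalized sets. In the contrast within the set of 5 the count was 0.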

How the results depend on the processing

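The contrast within the set of 5 arrays, the leaving out of homozygous replicate 4 from the set of 6 alone, and the list tests on the set of 6, on all 7 homozygous arrays and with the Gapdh covariate were chosen only after the result was seen. No paired analysis was possible because the replicate numbers only follow the order of the samples. Robo2 stayed lower in 26 alternatives, from -1.12 to -0.45 (-1.08 to -0.81 with 1 array left out), and never passed, with adjusted p from 0.207 to 1. It has 1 named probe set, so testing its probe sets separately added nothing, and the filter on dim genes removes Robo2, Spdye4a and Eml6. The genotype gene count was 1 with array weights (limma adjusted p = 0.0105), 1 at an adjusted p under 0.1 and 1 with all 7 homozygous arrays and the title series as a random effect (0.0133); the gene was Syt13, whose adjusted p ran from 0.0105 to 1. Leaving out any 1 array gave 0 genes. With all 7 homozygous arrays and no title series term, Tgfa (0.018), Tnfaip2 (0.10) and Zfp612 (0.21) reversed, by construction across the normalized sets. In that fit the medians of 6 lower lists turned positive while their camera direction stayed down: proximal tubule (0.33), principal cells (0.19), intercalated cells (0.12), basement membrane (0.084), loop of Henle (0.064) and distal tubule (0.064), and only distal tubule kept its call. Genotype lists numbered 0 with an estimated correlation, 0 in fry, and 16 to 20 with 1 array left out. Smooth muscle reversed to -0.20 without homozygous replicate 4 and ran up to 0.85 with 1 array left out. Leaving out wild-type or homozygous replicate 1 gives one and the same genotype fit, because the partner then carries no genotype information.

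The NB-titled gene count was 4773 after quantile normalization, 7151 with median centring, 37458 with all probe sets, 0 without a title series term, 0 with the 7 arrays alone and 0 within the set of 5; with 1 array left out it ran from 14550 to 16211. More features explain the count over probe sets; the cause of the others was not tested beyond the shift between the sets. Its lists numbered 0 with an estimated correlation, 35 in fry, which does not compare lists with other genes, and 14 to 18 with 1 array left out. With the Y-linked mean as a covariate Kdm5d (-1.40) and Xist (3.26) reversed, by construction. In the contrast within the set of 5, Pck1 (-0.070), erythroid genes (0.38) and nerve (1.36) reversed. For urothelium (0.30), adrenal gland (1.47) and liver (2.05) only the direction of the camera test did, and the medians kept their sign. Without homozygous replicate 4 smooth muscle reversed to 0.35, and so did the camera direction for urothelium (0.47). Over the fits with 1 array left out urothelium ran from 0.076 to 0.47 and smooth muscle from -0.48 to 0.35; the cause of these was not tested. Of the other named results, 236 of 241 gene and 234 of 288 list values of the genotype comparison kept direction and side of the threshold, as did 389 of 495 and 167 of 196 in the NB-titled comparison. For lists this is the direction of the camera test: among those kept the median changed sign for distal tubule in the fit named, liver without NB-titled replicate 2 (-0.66) and nerve without homozygous replicate 4 (0.06). Dim signal limits what was read for Robo2, at percentiles 3.37 to 38.1 of its array in the set of 6.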

Other observations

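The comparison of the normalized sets and the count of kidney lists over splits were chosen only after the result was seen. Single tubule genes and an embryonic globin gene differed between the set of 5 and the set of 6 arrays beyond the shift of all genes, on arrays of both genotypes. Relative to the array median, Kap stood at 4.49 ± 0.36 (SD, n = 5) in the set of 5 and at 0.14 ± 0.54 (SD, n = 6) in the set of 6, on the log2 scale. The gluconeogenic genes G6pc (2.16 ± 0.46 against -1.75 ± 0.34) and Pck1 (2.46 ± 0.48 against -1.12 ± 0.28) and Umod (4.10 ± 0.51 against 1.56 ± 0.62) were higher on each array of the set of 5 than on any of the set of 6. Hbb-y, the embryonic beta-like globin, was the reverse, at -3.64 ± 0.85 against 1.59 ± 0.12. The sets were normalized apart, so these are differences between arrays and not a tested effect of any group.

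In the R2E17 arrays all 37 proximal tubule genes lay above the shift, with a median of 1.68. Distal tubule genes were at 0.98, intercalated cell genes at 0.99, loop of Henle genes at 0.92, interferon response genes at 0.80 and endothelial genes at 0.46. Cell cycle genes were at -0.13 and fetal genes at -0.46. In the NB-titled arrays the values were 1.82 for proximal tubule, -0.30 for cell cycle and -0.53 for fetal genes. Camera called 12 lists between the R2E17 and E17R2 arrays. Its t values held the shift of all genes here too. Lists of genes that vary widely between arrays can thus be called lower whatever their level, and lists above the shift can miss the threshold. Not among them were proximal tubule (camera adjusted p = 0.105), loop of Henle (0.179), distal tubule (0.265) and intercalated cells (0.304). With an estimated correlation 0 lists passed in camera (smallest adjusted p = 0.0996, for fetal genes). Peripheral nerve (-2.54), liver (-1.62) and adrenal genes (-1.51) were lower in the R2E17 arrays.

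Traces of neighbouring organs varied from array to array in every group. Dazl, a germ cell gene, read 6.06 in homozygous replicate 2 and at most 4.72 elsewhere. The steroid-producing enzyme gene Cyp11a1 read 9.74 in NB-titled replicate 2, 8.02 and 7.74 in wild-type replicates 2 and 3 and 7.87 in homozygous replicate 2, and at most 4.72 in the other arrays. These log2 intensities include the shift between the sets. Relative to the mean of its set, homozygous replicate 2 had the adrenal list at -0.13 and the gonad list at 1.51. Which organ gave its Cyp11a1 signal was not determined. Brain genes did not pass in the genotype comparison (list median -0.01, camera adjusted p = 0.97), and neither did pancreas (0.05, 0.127), adipocyte (-0.05, 0.459) or peripheral nerve genes (0.07, 0.981). The brain result does not bear on the free-text labels, since tissue shared by both genotypes would give no difference. Between the R2E17 and E17R2 arrays the brain list was at -0.56 (camera adjusted p = 0.0151, and 0.163 with an estimated correlation). Of the remaining lists in the genotype comparison, hypoxia had a median of 0.15 (camera adjusted p = 0.111), immediate early genes 0.08 (0.515), injury genes -0.05 (0.597), mesangium and pericytes -0.03 (0.439), TGF beta and BMP signalling 0.04 (0.245), axon guidance 0.00 (0.628), housekeeping genes -0.01 (0.873) and Y-linked genes 0.15 (0.873).

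When the 10 kidney lists that were lower in homozygous kidneys were counted over the 35 splits of the 8 arrays, the real split moved 10 of them in one direction and the highest other split 9. These lists had been chosen because they moved, so the count is a hypothesis to test on other samples and excludes nothing.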
